A study of Caenorhabditis elegans with 2 samples.

How the data were processed

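Chromatin immunoprecipitation with sequencing (ChIP-seq) was done on whole L1 larvae of the Caenorhabditis elegans strain OP344. Per the labels, this strain has an unc-119 mutation and carries a transgene with efl-3 (sequence name F49E12.6) fused at its C-terminus to GFP and FLAG tags, together with a rescuing copy of unc-119. The immunoprecipitation used an antibody against GFP, and the larvae were of mixed sex, 6 hours of age, synchronised by starvation after bleaching. There was 1 group with 2 biological replicates, so no comparison between groups was made. The replicate numbers are those given in the labels.

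The authors' processing ended in 4 peak lists on the ce11 build, per the labels. They comprise 1 list for each replicate, 1 called on the replicates pooled, and 1 that the authors thresholded by the irreproducible discovery rate (IDR), a measure of how alike 2 ranked lists are. The last is called the reproducible set here, after the authors' own name for their step. Every list of a replicate and the pooled list held exactly 30000 peaks, so these lists are relaxed calls that reach far into the background. Each peak has a deposited signal value, which is the peak caller's measure of enrichment, and a deposited −log10 of a q-value. The deposited offset of the summit from the start of the peak gave the position used throughout. In most peaks it is the middle of an interval of fixed width, with a median width of 380 bp in the pooled list. All lists were made against the same control alignment, per the deposited file descriptions. The aligner, the peak caller, its settings and the IDR threshold are not given in the sources used here. The control library and the read depth were not analysed here. Depth is therefore unknown, and no interval that needs it is given. Signal values were used only to rank and describe peaks within a list.

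The 430 peaks of the reproducible set were exactly the 430 strongest peaks of the pooled list by signal value. The weakest of them had a signal of 94.83, and the next pooled peak 94.78. The set is thus a threshold on the pooled signal, and membership of a single peak says nothing of its own about how alike the replicates were at that peak. For this reason replicate ranks are given for some of the strongest peaks and for named bound list members whose peak ranked below the 430 strongest of a replicate. The largest −log10 q in the pooled list, 1.94, was shared by 132 peaks, so ranks rest on the signal value. In the reproducible set, 259 peaks had a q-value below 0.05 in that column and 367 below 0.1.

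Gene positions came from Ensembl release 115 for WBcel235, the same assembly as ce11, and sequence from the reference genome of that assembly. No peak ended beyond its chromosome. A promoter window ran from 1000 bp upstream to 500 bp downstream of any annotated start of a protein-coding transcript, and a gene with a reproducible summit in it was called bound. The background comprised 19973 protein-coding nuclear genes. Binding was tested for 24 gene lists, 16 of them written out by symbol and 8 defined by symbol patterns, with the two-sided Fisher exact test and Benjamini-Hochberg adjustment over the lists. Divergent genes can share a peak, so a second test counted each peak once per list against 10000 random lists. For the relaxed peaks, the median over a list's members of the largest pooled signal in the window (0 where there was no peak) was set against 10000 random lists of the same size, two-sided.

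Replicate summits within 100 bp of a reproducible summit counted as matched. Shares were set against 1000 random placements of the summits on the same chromosomes, for which the smallest possible p is 0.001. The correlation of log10 signal was tested with 100000 permuted pairings, and the X chromosome share with an exact binomial test. Motif matches on either strand were counted within 100 bp of each summit. The controls were up to 20 windows per peak at the same signed distance from starts of unbound genes, with a GC content within 2.5 percentage points. All 20 were found for 425 of the 430 peaks, which gave 8540 control windows. Each of 1000 draws took 1 window at random from a peak's own window and its controls, which gives a two-sided p of at least 0.002. An earlier form of the draws left out the peak's own window. It gave a smaller p for the E2F consensus, on the same side of the threshold, and was replaced after it had been run on the data because it passed the threshold too often on simulated windows without a planted motif. Benjamini-Hochberg adjustment covered 11 motifs, 3 of which were reordered versions of the E2F consensus. Intervals of shares are 95% Wilson intervals over peaks. Peaks are not independent replicates, so p-values over peaks or genes describe these lists and not the spread between worm cultures.

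The genes named were fixed by a rule before the data were examined. They are efl-3, unc-119, egl-1 and lin-39 whatever their values, the genes with the start nearest to the 15 strongest reproducible peaks, and for each list up to 5 bound members with the strongest peaks. Genes outside this rule are marked as named after their values were seen. Some bound members of the chemoreceptor list are not reported here by name. The tests, gene lists, motifs and most alternatives were also fixed then. The alternatives changed the promoter window, the peak set, the matching distance, the control windows, the motif and the background, and replaced the set by the 430 strongest peaks of either replicate alone. Restricting promoter share, list binding and motif share to peaks that were strong in both replicates was chosen after seeing the data, as were assignment to the nearest start within the promoter window and the expectations of chromosomes other than X.

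The tests were tried on simulated data. A list of 50 genes with 6 members added to a random bound set was found in 50 of 50 trials over 19973 genes, and 2 of 1150 lists without added members passed the threshold. A motif planted in 6% of 430 windows was found in 99 of 100 trials, and 5 of 100 unplanted trials had a p below 0.05. The correlation test found 20 of 20 planted correlations and called 2 of 20 unplanted pairs. The search for 50-base words with another copy found both of 2 copied windows and called 0 of 1 single window, a small trial. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.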

Results

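Binding of the tagged E2F family protein EFL-3 was mapped in whole L1 larvae from 2 biological replicates. The E2F family comprises transcription factors known for control of the cell cycle, and EFL-3 is an atypical member related to mammalian E2F7 and E2F8. In earlier work EFL-3 was linked to repression of the cell death gene egl-1 together with the Hox protein LIN-39. The design holds a single group, so the questions are where EFL-3 peaks lie, which gene groups have them in their promoters, whether an E2F site is present, and how alike the replicates are. Coordinates are on ce11. The signal value is the peak caller's measure of enrichment and has no unit.

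The reproducible set held 430 peaks with signal values from 94.8 to 508.5. The strongest summit, at position 11374449 of chromosome I, lay in intergenic sequence 115 bp upstream of F56G4.6, with a signal of 508.5 and ranks of 1 and 3 in replicates 1 and 2. The next, at 3867567 on chromosome III, lay 287 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit, with a signal of 506 and ranks of 3 and 1. The peak ranked 4, at 4049713 on chromosome IV, lay 265 bp upstream of pcn-1, which encodes the DNA polymerase sliding clamp PCNA. Its signal was 400, its ranks in the replicates were 4 and 10, and it held an E2F consensus match. The peak ranked 5, at 9988977 on chromosome I, had a signal of 393 and lay 155 bp upstream of the histone gene his-68. It was also in the promoter windows of his-67 and alg-5 (the latter named after its values were seen).

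Among the 15 strongest peaks, 10 lay in a promoter window. The other promoter peaks of this group were nearest to the starts of Y56A3A.7, egg-5, the ribosomal protein gene rpl-35, sec-61.G (a subunit of the protein translocon), Y17G9B.5 and the fatty acid synthase gene fasn-1. Their signals ran from 373 for Y56A3A.7 to 335 for fasn-1. The remaining 5 lay outside promoter windows. The peak ranked 3, with a signal of 484, was in an intron of ppfr-1, 6426 bp downstream of its nearest start, at 9383158 on chromosome I. It ranked 2 in replicate 1 and 43 in replicate 2. An intronic peak at 8500556 on chromosome V was 5667 bp downstream of a start of the peroxidasin gene pxn-1. Intergenic peaks lay 4024 bp downstream of the start of W02H3.3 at 11094162 on X, 6030 bp upstream of K02D3.1 at 13700877 on X, and 3008 bp upstream of ztf-27 at 10382325 on chromosome II. The peaks nearest to ppfr-1, pxn-1 and egg-5, ranked 3, 7 and 10, also lay within 200 bp of annotated noncoding RNA genes. These were an ncRNA, a snoRNA and an snRNA gene, respectively.

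The replicates shared much of this set but not all of it. Of the 430 summits, 329 (76.5%) were within 100 bp of one of the 430 strongest peaks of replicate 1 and 309 (71.9%) of replicate 2. For 238 (55.3%) this held in both replicates, against 0.0512% for random placements (permutation p = 0.001, the smallest possible). Against all 30000 relaxed peaks of each replicate, 405 summits (94.2%) were matched in both. Over these 405 peaks the log10 signal of the replicates was correlated across peaks, with a Spearman rho of 0.530 and a Pearson r of 0.594 (permutation p = 1e-05 for each, the smallest possible). Both replicates contributed to the authors' set, so this overlap is not independent evidence. The relaxed lists themselves overlapped less, with 7344 of the 30000 peaks of replicate 1 (24.5%) within 100 bp of a peak of replicate 2. Replicate 1 had 352 peaks with a q-value below 0.05 and replicate 2 had 198.

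**Figure D1:**
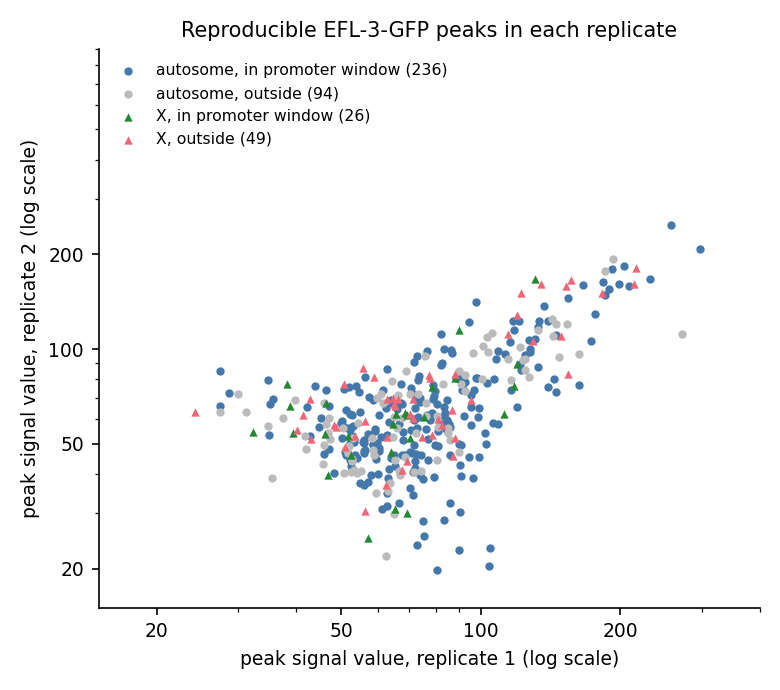
Signal value of each reproducible peak in replicate 1 (x axis) and replicate 2 (y axis), both without unit and on log scales, for the 405 peaks matched within 100 bp in both; color and shape mark autosome or X and promoter window or outside. Spearman's rho over these peaks was 0.530.

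Most reproducible summits were upstream of genes. In all, 276 of 430 (64.2%, 95% Wilson interval 59.5 to 68.6%) lay in the promoter window of a protein-coding transcript, against 31.4% for random placements (permutation p = 0.001, the smallest possible). Among the other pooled relaxed peaks the share was 34.1% (Fisher exact p = 2.48e-36). By annotation, 60.7% of summits were intergenic, against 33.2% at random, and 21.9% were in introns, against 33.99%. Coding exons held 3.02% of summits, against 24.3% at random, and annotated noncoding genes held 9.30%, against 3.65%. The promoter windows with a summit belonged to 386 genes, 1.93% of the 19973 protein-coding genes, and 108 peaks lay in the windows of more than 1 gene.

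Peaks were unevenly spread over the chromosomes. Chromosome III had 87 peaks where 56.8 were expected from its share of protein-coding genes (exact binomial test, adjusted p = 0.00018 over 6 chromosomes), and chromosome V had 63 where 107.5 were expected (adjusted p = 1.16e-06). X had 80 peaks, 18.6% of the set (95% Wilson interval 15.2 to 22.6%), against 13.7% of genes (exact binomial p = 0.00395, two-sided; adjusted p = 0.0079). These departures depend on the expectation. X holds 17.7% of the genome's length (exact binomial p = 0.613) and 16.5% of pooled relaxed peaks (p = 0.243). From length, 59.1 peaks were expected on III (adjusted exact binomial p = 0.00117) and 89.7 on V (0.00393). From pooled relaxed peaks, 72.9 were expected on III and 79.5 on V, and no chromosome passed the threshold (adjusted exact binomial p = 0.216 for both). On X, 53 of the 80 peaks (66.2%) lay outside promoter windows, and on the autosomes 101 of 350 (28.9%) did so, with a sample odds ratio of 4.84 (Fisher exact p = 9.21e-10). This last comparison and the tests of chromosomes other than X were chosen after seeing the data.

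**Figure D2:**
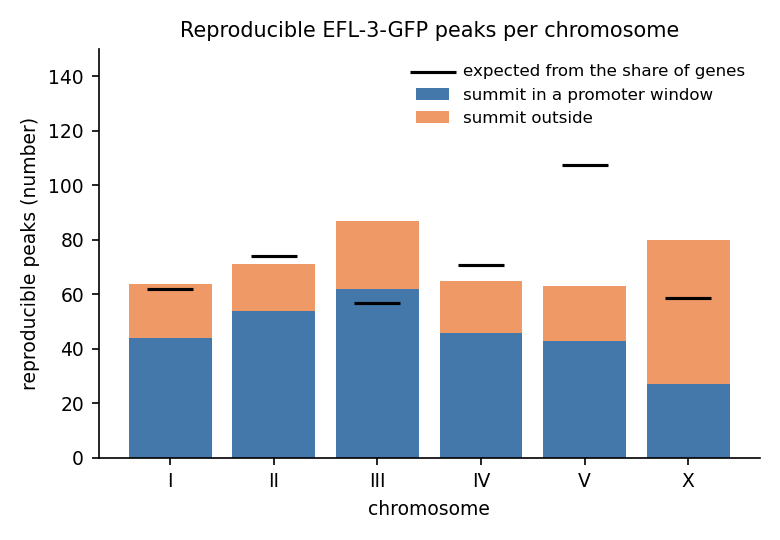
Number of reproducible peaks (y axis) on each chromosome (x axis), split into summits in and outside promoter windows; black lines mark the number expected from each chromosome's share of protein-coding genes. On X, 53 of 80 peaks lay outside promoter windows.

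Genes of DNA replication were bound more often than other genes. Of the list for replication and nucleotide supply, 6 of 42 genes had a reproducible summit in the promoter window, where 0.812 were expected (Fisher exact test, adjusted exact p = 0.000701). Besides pcn-1 these were rpa-2 (replication protein A; signal 170), mcm-2 (replicative helicase; signal 167), rfc-4 (clamp loader; signal 114), pole-1 (DNA polymerase epsilon; signal 111.97) and mcm-10, the last named after its values were seen. The strongest peaks of replicate 2 alone gave 4 such genes and those of replicate 1 alone 8. In replicate 2 the pole-1 peak ranked 524 and the mcm-10 peak 16255. The E2F, Rb and DREAM list had 4 of 26 genes bound where 0.502 were expected (adjusted exact p = 0.00586). All 4 encode parts of the Rb-like DREAM complex. They were lin-9 (signal 187.7, summit 124 bp upstream of the start), lin-35, the worm Rb protein (148, 191 bp upstream), lin-53 (145, 233 bp upstream) and lin-54 (135, 375 bp upstream). In replicate 2 the lin-35 peak ranked 442 and the lin-54 peak 611. Among the 238 peaks that were strong in both replicates, 2 of the 26 genes were bound and the call was lost (adjusted exact p = 0.136).

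Genes for protein synthesis and folding formed another bound group. Of the cytosolic ribosomal protein genes, 14 of 77 were bound where 1.49 were expected (adjusted exact p = 2.68e-09), and with the strongest peaks of replicate 2 alone 9 of 77 (adjusted exact p = 2.97e-05). The strongest after rpl-3 and rpl-35 were rpl-20 (signal 343), rps-1 (222) and rpl-15 (215). Chaperone genes had 11 of 58 members bound where 1.12 were expected (adjusted exact p = 7.38e-08). They were led by hsp-60, the mitochondrial chaperonin (signal 333), hsp-90 (253), cct-8 (237) and cct-1 (186), subunits of the cytosolic chaperonin, and dnj-29 (158). Each of these named chaperone peaks was nearer to the start of another gene. The hsp-60 peak, for instance, lay 610 bp from the hsp-60 start and 203 bp from that of another gene. With every peak, in a promoter window or not, assigned only to the gene with the nearest start, 4 of the 58 chaperone genes and 7 of the 77 ribosomal protein genes had a peak. The first call was lost (adjusted exact p = 0.118) and the second kept (adjusted exact p = 0.00739). With the nearest start and the promoter window both required, an alternative chosen after seeing the data, the same counts gave an adjusted exact p of 0.0313 and 0.000655.

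Of the histone genes, 16 of 59 were bound where 1.14 were expected (adjusted exact p = 3.43e-13), and with the strongest peaks of replicate 1 alone 10 of 59 (adjusted exact p = 6.91e-07). Many histone genes lie in divergent pairs that share a promoter, and the 16 genes corresponded to 10 distinct peaks, where 1.15 were expected (adjusted permutation p = 0.0012). With every peak assigned only to the gene with the nearest start, 9 of the 59 had a peak (adjusted exact p = 3.13e-05), and as many with the promoter window also required (adjusted exact p = 2.21e-06). The peak of his-31 and his-32 had a signal of 197, and that of his-59 a signal of 153. Histone genes exist in near-identical copies. Of the 10 histone peaks, 2 held any 50-base word with another copy in the genome, with a share of 2.63% of words at the peak of his-5 and his-6 (rank 494 in replicate 1) and 90.1% at that of his-42 (ranks of 7751 and 145 in replicates 1 and 2), all 3 named after their values were seen. Reads at his-42 could therefore have come from another copy.

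Chemoreceptor genes, which act in sensory neurons, were bound less often than other genes, with 3 of 1353 bound where 26.1 were expected (adjusted exact p = 7.23e-08), and with the strongest peaks of replicate 1 alone 1 (adjusted exact p = 2.40e-09). Among them was sri-5 (signal 114.6, with ranks of 197 in replicate 1 and 1240 in replicate 2). The other lists did not pass the threshold, and the small expected numbers leave little room to detect fewer bound genes. The DNA damage list had 3 of 43 genes bound (adjusted exact p = 0.15), with lig-4, a DNA ligase (signal 304), and hpr-9 (172) and mrt-2 (103; rank 475 in replicate 1), both of the checkpoint clamp. Developmental timing had 2 of 17 (adjusted exact p = 0.143), nhl-2 (283) and lin-28 (105, with rank 658 in replicate 2), and 3 of 17 with replicate 1 alone (adjusted exact p = 0.012). The nhl-2 peak lay 840 bp from the nhl-2 start and 583 bp from that of another gene. The Wnt, Notch, EGF and TGF-beta list had 3 of 54 (adjusted exact p = 0.231), namely the beta-catenin gene wrm-1 (112.5), sma-9 (107; rank 4785 in replicate 2) and the Nemo-like kinase gene lit-1 (100; rank 637 in replicate 2).

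Single members were bound in 5 further lists. These were ced-5 of cell death and engulfment (1 of 34; signal 172), the epidermal GATA factor elt-1 of the epidermis list (1 of 41; 170), epg-2 of the insulin, starvation and autophagy list (1 of 50; 97.6; rank 1897 in replicate 2), col-63 of the collagens (1 of 175; 128; not matched in replicate 1) and ins-39 of the neuropeptides and insulin-like genes (1 of 140; 194). Nuclear hormone receptors had 2 of 274 bound, nhr-47 (129) and nhr-34 (110). No gene was bound among 42 cell cycle regulators, 11 Hox genes and cofactors, 42 neuronal fate factors, 96 homeobox genes, 27 pan-neuronal genes, 32 genes of body wall muscle, 33 of intestine, 23 of pharynx and 38 of germ line. Of the 24 lists, 5 were bound more often and 1 less often at an adjusted p under 0.05.

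**Figure D3:**
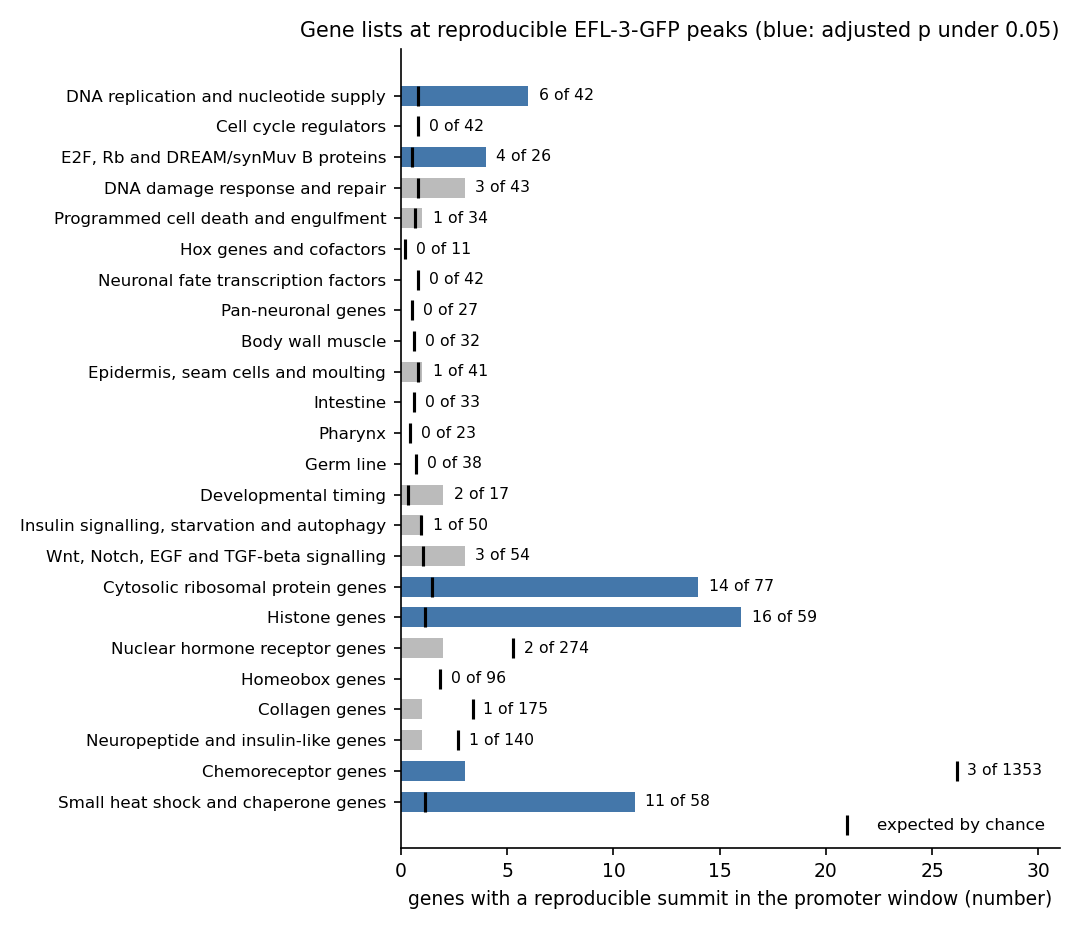
Number of genes with a reproducible summit in the promoter window (x axis) for each of 24 gene lists (y axis); black ticks mark the number expected by chance, and blue bars have an adjusted p under 0.05 by Fisher's exact test. Histone genes (16 of 59) and ribosomal protein genes (14 of 77) lie far above the ticks, and chemoreceptor genes (3 of 1353) far below.

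The relaxed pooled peaks, which reach below the reproducible threshold, gave higher medians than random lists for 6 of the 24 lists. Of all genes, 8707 had a relaxed peak in the window, so the median of random lists was 0. The list medians were 45.1 for cell cycle regulators (31 of 42 genes with a peak; adjusted permutation p = 0.0012), 44.1 for DNA damage response (27 of 43; 0.0012), 43.045 for replication (25 of 42; 0.00192) and 42.6 for the E2F, Rb and DREAM list (19 of 26; 0.016). Ribosomal protein genes had a median of 52.1 (66 of 77; adjusted permutation p = 0.0012) and developmental timing genes 53.9 (15 of 17; 0.0012). In the narrower window of 500 bp upstream to 200 bp downstream, 3 lists passed the threshold, namely developmental timing, ribosomal protein genes and the E2F, Rb and DREAM list, while the medians of cell cycle regulators, DNA damage response and replication were 0. With the relaxed peaks of a single replicate, the E2F, Rb and DREAM list passed the threshold in neither replicate. The DNA damage list passed it in replicate 1 but not in replicate 2. The rest of the 6 lists passed it in both. The medians of the 6 lists, from 42.6 to 53.9, lay below the weakest reproducible signal. The pooled list's median over all its peaks was 41.6. It is an unlike measure, since the list medians use each gene's largest peak and 0 for no peak. A list median above 0 needs only that most members had a relaxed peak. The test therefore reflects the presence of relaxed peaks as well as their signal, and does not describe single bound genes.

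The E2F consensus TTTSSCGC was present at 32 of 430 summits (7.44%, 95% Wilson interval 5.32 to 10.3%), against 4.63% of matched windows (permutation p = 0.016, adjusted p = 0.0346). The excess was not specific to this order of letters. The reordered consensus TCTSGTSC was present at 5.12% against 2.38%, and STCGTSTC at 6.28% against 2.58% (adjusted permutation p = 0.0073 for each), while CGTSTTSC was at 2.33% against 2.67% (adjusted permutation p = 0.938). Peaks with the E2F consensus tended to be stronger, with 9.77% among the 215 strongest and 5.12% among the 215 weakest (Spearman rho = 0.099, permutation p = 0.0395). With the strongest peaks of replicate 2 alone the share was 6.51% (permutation p = 0.11), and within 50 bp of the summit it was 2.79% against 2.57% in matched windows (permutation p = 0.875).

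Of the other motifs, GAGA repeats (7.91% against 3.97%, adjusted permutation p = 0.0073), the CHR element bound by DREAM complexes (43.95% against 36.9%, adjusted permutation p = 0.0165) and the SP1-like sequence CCGCCC (12.6% against 9.14%, adjusted permutation p = 0.0346) were more frequent at peaks. The intestinal GATA site CTGATAA was less frequent (1.40% against 3.45%, adjusted permutation p = 0.0346). The E-box CACGTG (7.44% against 5.09%, adjusted permutation p = 0.055), the CRE site (0.698% against 1.62%, adjusted permutation p = 0.234) and the PBC-Hox site (11.6% against 11.96%, adjusted permutation p = 0.963) did not pass the threshold.

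**Figure D4:**
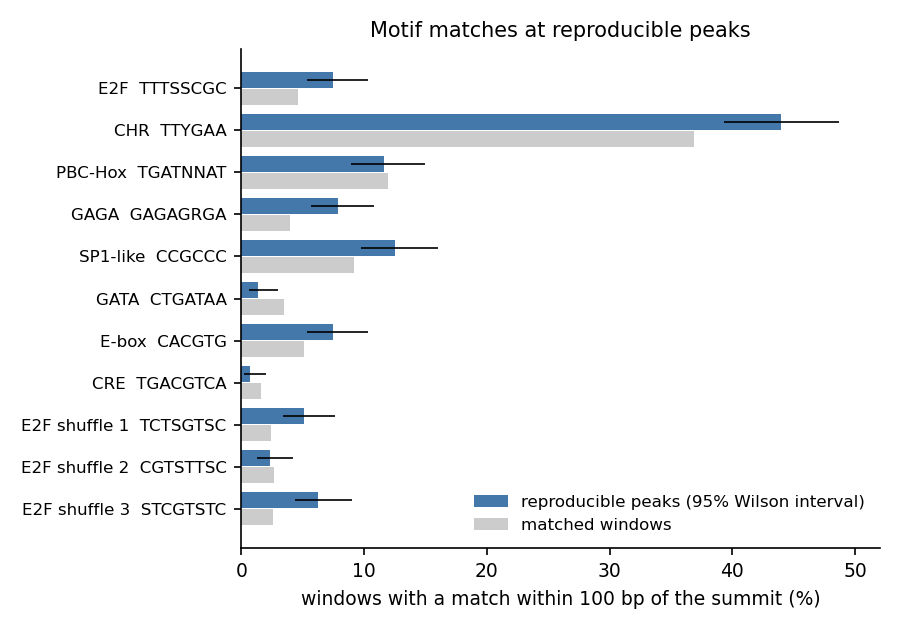
Share of windows within 100 bp of the summit that hold each motif (x axis, percent) at reproducible peaks (blue, with 95% Wilson intervals over 430 peaks) and in matched windows (grey), for 11 motifs (y axis). The E2F consensus is at 7.44% against 4.63%, and 2 of its 3 reordered versions also exceed their matched windows.

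The efl-3 gene itself, at 8412671 to 8416857 on the forward strand of chromosome II, had 3 reproducible peaks within 5000 bp. The strongest, in an intron at 8415663, had a signal of 204 and ranked 72, with ranks of 88 in replicate 1 and 54 in replicate 2. Both others were intergenic upstream, at 8409696 (signal 129) and 8410486 (signal 107). None of these summits lay in the promoter window of efl-3, so efl-3 was not bound by the definition used here. The starts nearest to the summits at 8415663 and 8409696 were those of other genes. The strain carries efl-3 also on the transgene, and the peak lists do not separate the endogenous gene from the transgene. At unc-119, which has a rescuing copy of unstated origin on the same transgene, the strongest pooled peak ranked 3516, with a signal of 58.2. At egl-1 the strongest pooled peak within 5000 bp, at 14433860 on chromosome V, ranked 2582 (signal 61.8). The strongest replicate 1 peak, at 14433895, ranked 1808. In replicate 2 the peak at this site, at 14433850, ranked 22868 (signal 20.4). The strongest replicate 2 peak within 5000 bp of egl-1 was at another site, 14429755 in a coding exon, and ranked 6272. At lin-39 a peak in a 5' UTR at 7534762 on chromosome III had a signal of 93.6 and ranked 456, just below the reproducible set. In the replicates the strongest lin-39 peak ranked 447 and 1010.

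**Figure D5:**
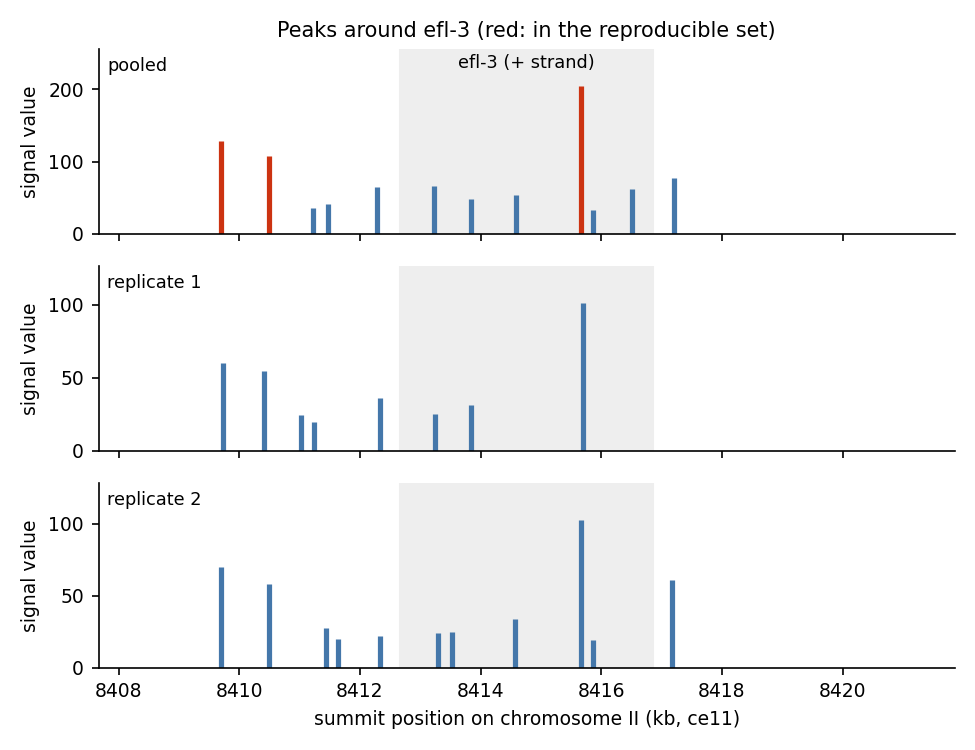
Peak summits around efl-3 in the pooled list and in each replicate, by position on chromosome II (x axis, kb) and signal value (y axis, without unit); the grey area is the gene and red lines are peaks of the reproducible set. The intronic peak is the highest in all 3 lists, at 204 in the pooled list.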

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

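Of 134 alternative values, 41 of main results and 84 of single lists or replicates were counted as unchanged. For results with a test, this means the same direction and the same side of the threshold. For numbers of lists it means only a number near the main one, so single lists could be lost or gained. Using the strongest pooled peaks in place of the reproducible set moved nothing, because both hold the same 430 peaks. The values of this alternative could not change, and they are counted among the unchanged ones. For promoter share, list binding and motif share, the restriction to peaks strong in both replicates was chosen after seeing the data, and for list binding also the assignment to the nearest start within the promoter window; the other alternatives, the stricter set's count included, were fixed before. The promoter share stayed above random placement under every alternative tried, with 57.7% to 62.1% for the strongest peaks of a single replicate. The number of lists called was 6 or close to it under all alternatives, from 5 to 7, and the results on single lists that were lost or gained are given with those lists in the report. A stricter set of peaks strong in both replicates held 238 of the 430, because its construction takes peaks away. The X share of 18.6% no longer passed the threshold against chromosome length or against relaxed peaks, since these expectations are higher than the share of genes. The number of lists with a higher signal in relaxed peaks was 3 in the narrower window, which leaves fewer genes with a peak (5209 in place of 8707), and 4 to 8 in single replicates. The E2F share was 6.51% to 7.44% in single replicates and no longer passed the threshold in replicate 2 alone; within 50 bp of the summit it was 2.79%, no longer past the threshold. The cause was not tested for these. Read depth is unknown, so which replicate is more precise cannot be said, and replicate 1 had more peaks with a q-value below 0.05. No paired analysis was possible because there is 1 group.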

Other observations

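The tests in this part were chosen after the peaks had been seen, except those on repeated sequence and on other antibodies, which were written down before their results. The first test of the region around efl-3 was written down when the peaks within 5000 bp, but not the wider region, had been seen. The second was added after the result of the first.

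Small noncoding RNA genes were a further class near EFL-3 peaks. Within 200 bp of annotated snRNA genes lay 14 reproducible summits, where random placement gave a mean of 0.267, and within 200 bp of snoRNA genes 20, against 0.81. Near tRNA genes lay 17, against 1.24, and near genes annotated as ncRNA 85, against 15.1 (permutation test, two-sided, adjusted p = 0.0035 for each over 7 classes); near miRNA genes lay 4, against 0.566 (adjusted permutation p = 0.008). Random placement does not allow for the promoter windows of protein-coding genes, where most of the ncRNA and snRNA summits lay. Outside promoter windows were 33 of the 85 ncRNA summits, 5 of the 14 snRNA summits, 11 of the 20 snoRNA summits and 15 of the 17 tRNA summits, 10 of the last on X. The strongest summit ranked 3 near ncRNA genes (the ppfr-1 intron), 7 near snoRNA genes (the pxn-1 intron) and 10 near snRNA genes (upstream of egg-5). Pseudogenes had 4 summits nearby, against 16.04 (adjusted permutation p = 0.0056), and piRNA genes 3, against 12.4 (adjusted permutation p = 0.008). The series holds no mock or other-antibody sample. Sites near noncoding genes that any immunoprecipitation recovers therefore cannot be told apart from binding of EFL-3.

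A long sequence recurred at autosomal promoter peaks. Among 8192 words of 7 bases, 247 had an adjusted p below 0.05 at the 350 autosomal peaks. The smallest was that of CCTCTCG, at 48 of them (13.7%) against 1.95% of matched windows (Fisher exact test, adjusted p = 2.33e-19, one-sided). The longer form CTCCTCTCGG was found at 27 peaks, including the strongest of the set upstream of F56G4.6. All 27 lay in promoter windows on autosomes, and 5 also held the E2F consensus. Of its 356 matches in the genome, 30 (8.43%) were within 100 bp of a reproducible summit. The longer form was picked at these same peaks, so this share describes them and was not tested. Most matches, therefore, had no reproducible peak. This word is not in the motif list fixed at the start, and no factor is named for it here.

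A word known from X recurred at X-linked peaks outside promoter windows. The word GCGCAGGG, the core of a sequence known from sites that recruit the dosage compensation complex to X, was present at 12 of these 53 peaks (22.6%, 95% Wilson interval 13.5 to 35.5%), at 2 of 27 X-linked peaks in promoter windows (7.41%, 2.06 to 23.4%; Fisher exact p = 0.123 against those outside), at 1 of 101 autosomal peaks outside promoters, and at 8 of the 12 such X peaks among the 50 strongest peaks. Sites included the peaks nearest to W02H3.3 (rank 6), xol-1 (rank 17, at 8036384), cest-16 (rank 18) and Y41G9A.17 (rank 19), named after their values were seen. The tables argue against the lower density of gene starts on X as the cause. The odds ratio of lying outside promoters, X against autosomes, was 1.22 among the weaker pooled peaks. Among reproducible peaks it was, as a conditional estimate, 4.82 (95% interval 2.80 to 8.45). None of 1060 X windows of matched GC content held the word (Fisher exact p = 1.23e-12 after multiplication by the 32896 words of this length). The multiplication was made since the word was noticed at these peaks. This argues against the GC content of X as the reason for the word at 12 of the 53 peaks. It cannot decide why X-linked peaks lie outside promoters, since most of them lack the word. The promoter windows are those of protein-coding genes only. Of the 53 summits, 10 lay within 200 bp of tRNA genes and 13 within 200 bp of ncRNA genes. On the autosomes 5 and 20 of the 101 did so, respectively. A summit can be near both classes. A candidate explanation is that a part of the X-linked peaks outside promoters lies at sites of dosage compensation complex recruitment. Against autosomal peaks the Fisher exact p was 1.06e-05 (the reversed letter order gave p = 1) and became 0.350 after the same multiplication. This correction was added after these results had been seen. It treats the word as picked from all words of its length, though the word was known beforehand. In the search of 7-base words, CCCTGCG, part of this word on the other strand, had the smallest adjusted p at the 80 X-linked peaks. It was at 16 of them (20%) against 0.380% of matched windows (Fisher exact test, adjusted p = 9.17e-14, one-sided). The explanation stays open, because a word match alone does not show recruitment. Whether these are sites recovered by any immunoprecipitation cannot be told apart from binding of EFL-3, as 0 mock or other-antibody samples are in the series.

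The E2F consensus was unevenly spread over the promoter peaks of the lists. The first group comprised peaks of the ribosomal protein, chaperone and histone lists. The second group comprised those of the replication list and of the E2F, Rb and DREAM list. The consensus was present at 3 of 34 peaks of the first group (8.82%, against 5.63% in matched windows, permutation p = 0.297). In the second group it was present at 5 of 10 peaks (50%, 95% Wilson interval 23.7 to 76.3%, against 5%, permutation p = 0.001). The matched windows came from unbound genes of any kind. Unbound members of these lists were not scanned as a set, so a share due to the peaks cannot be told apart from one due to the gene class. The reordered versions of the consensus were not counted in these groups. Both permutation p-values are one-sided, so the two-sided minimum of 0.002 given for the motif draws does not apply to them. The difference between the groups had a Fisher exact p of 0.0092, on few peaks. The peak ranked 182 is shared by lin-54 and rpl-12 (the latter named after its values were seen) and holds the consensus. It counts with the second group here. Placed with the first group, the counts were 4 of 35 and 4 of 9 (Fisher exact p = 0.0422), and left out of both, 3 of 34 and 4 of 9 (Fisher exact p = 0.0257), so the size of the difference depends on this peak. By list, the consensus was at 1 of 14 ribosomal protein peaks, 2 of 11 chaperone peaks, 1 of 10 histone peaks, 2 of 6 replication peaks and 3 of 4 E2F and DREAM peaks. Against the first group, the replication peaks alone had a Fisher exact p of 0.154 and the E2F and DREAM peaks alone 0.00887, so the difference rests mainly on the latter. The median share of 50-base words with another exact copy in the genome was 0% in each of the 3 lists of the first group. However, 1 of the 10 histone peaks lay mostly in repeated sequence. These shares argue against reads shared between exact copies as the common cause. Copies without an identical run of 50 bases were not searched for, so sharing between near-identical copies stays open. Most peaks of the first group had no consensus match within 100 bp of the summit. Their share with a match was not shown to differ from matched windows. The peaks are too few to say how far the groups differ. Whether the promoters of the first group were recovered through EFL-3, a partner or the open state of highly transcribed promoters was not tested.

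The peaks around efl-3 may reflect extra copies of the efl-3 region in the strain. The weaker pooled peaks within 15000 bp of efl-3, 16 in number, had a median signal of 51.1, at the 97.8th percentile of protein-coding genes, but those within 5000 bp had been seen before and make up most of them. The other 7, between 5000 and 15000 bp away, had a median of 44.9, at the 75.8th percentile, so neither extra copies nor their absence can be read from them. Only 10 genes, efl-3 among them, had 3 or more reproducible peaks within 5000 bp. Binding of EFL-3 at its own gene remains open, since a cluster of bound sites would also raise its neighbours, and the ends of the transgene insert are not given in the sources used here. The design holds 1 group, so no biological explanation was tested for any of these patterns beyond the sequence tests.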
